A study of Mus musculus with 22 samples.

How the data were processed

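RNA was measured by poly(A) sequencing in 22 libraries of primary mouse hippocampal neural stem cells: 6 shLuc and 5 shOgt libraries in a knockdown arm, and 6 vehicle and 5 OSMI-1 libraries in an inhibitor arm, grouped by the sample labels. The labels do not say that libraries of a group came from separate animals or cultures. The p-values of tests on libraries thus measure the spread between these samples, which may be technical. Per the labels' extract protocol the libraries were strand-specific poly(A) libraries, whereas the series design text names Smart-Seq2, and this was not settled here. Per the submitters' processing notes the tools were STAR, RSEM and DESeq2, with no version given, and the genome build named there is human, although the tables carry mouse gene symbols. No coordinates of the authors' build were used.

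The authors deposited 1 table per arm with 24411 genes each. Per the file headers, each holds a base mean and normalized counts per library, that is gene counts divided by a DESeq2 size factor (a signal that is never negative), together with the authors' log2 fold change and its standard error, a Wald statistic (a score) and the p-value and adjusted p-value of each gene. The direction of the deposited log2 fold change was checked against the library values: it is shOgt over shLuc in 1 table and vehicle over OSMI-1 in the other, and all values here are treated over control. In each library all positive values were whole multiples of 1 step (100% within 0.001 of a whole number), so the reads were recovered, and their DESeq2 size factors equalled the deposited ones. Recovered reads per library ran from 7.22 to 13.2 M reads in the knockdown arm and from 4.52 to 12.8 M reads in the inhibitor arm, with 13482 to 16480 genes holding a read. Mean totals were 11.2 ± 1.28 M reads in shLuc and 9.44 ± 1.46 M reads in shOgt (exact permutation test, two-sided, p = 0.063), and 5.12 ± 0.517 M reads in vehicle and 6.74 ± 3.42 M reads in OSMI-1 (p = 0.25). The precursor ribosomal RNA entry Rn45s took 0.921 to 1.25% of reads in the knockdown arm and 4.81 to 14.2% in the inhibitor arm. No 2 libraries agreed within sampling noise: the smallest chi-square per degree of freedom between libraries was 5.86 in the knockdown arm and 3.74 in the inhibitor arm. On principal components, shLuc 1 and vehicle 1 stood apart on the second component of their arms, and shLuc 3, shOgt 3 and OSMI-1 5 on the third.

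Because the tables hold normalized counts, the test set for that case before the data were examined was used: limma with an intensity trend on log2(normalized count + 1), within each arm and without covariates. A fold change on this scale understates the change of genes with low counts. Genes were kept by edgeR's filterByExpr on the recovered reads (minimum count 10, minimum total 15), which left 12136 genes in the knockdown arm and 11349 in the inhibitor arm with 99.9% and 99.8% of reads. P-values were adjusted by Benjamini and Hochberg and called at 0.05, two-sided. Unadjusted, 5031 and 4038 genes lay below 0.05. Called on the recovered reads with edgeR's quasi-likelihood test, 3848 and 2804 genes passed. The authors' deposited table calls 4063 and 2964 genes, of which 3793 and 2763 are also called by limma, and DESeq2 rerun on the recovered reads gave those same numbers of calls. In the authors' deposited table for OSMI-1, Amd1 has a log2 fold change of -24.3 (vehicle over OSMI-1), with a value above 0 in 2 libraries, and such folds were not used.

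Gene lists (27) were fixed before the data were examined, together with the tests, the rule for named genes and the alternatives listed then. Lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01, adjusted over lists), and again with an estimated correlation; 13 mitochondrially encoded genes are not among the table entries, and the lists of microglia, vessel and ependymal markers had too few measured members for a test. The median, the mean and the camera direction of a list differed in sign for the O-GlcNAc, astrocyte and ribosomal lists after knockdown and for the astrocyte, oligodendrocyte, BMP, NRF2, glycolysis and immediate early lists after OSMI-1, none of which passed camera. Overlap of calls between the arms was tested with Fisher's exact test (one-sided for excess) among genes tested in both, and correlations of log2 fold changes have bootstrap intervals over genes (1000 draws, 95%). Differences between the arms were tested per gene with a normal test. Its score was the difference of log2 fold changes over the root of the summed squared standard errors. This test takes the standard errors as known, although few libraries lie behind them, so its smallest p-values are too small. Lists were tested with cameraPR on those scores.

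The text names Ogt, Oga (under its symbol Mgea5), Stat3, Gfap, Dcx, Sox2, Nes and Mki67. Per comparison it also names the 6 genes with the largest rise and the 6 with the largest fall among called genes in the upper part of expression, with each treated library on the same side of the control mean. Predicted genes and pseudogenes were left out there. It further names the 3 members of smallest p of each list that passed camera and of the stem cell, neuronal, astrocyte, oligodendrocyte, STAT3 and O-GlcNAc lists, some members of smallest p of other lists, and the 5 genes called in both arms with the largest smaller fold for each pair of directions. Genes named outside this rule are marked as such.

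The search for short sequences was chosen after the data were seen. For each of 15715 sequences of 7 bases found in the 3′UTRs of at least 100 tested genes (GENCODE M21, GRCm38, protein-coding transcripts, at least 50 bases of 3′UTR), the log2 fold change was regressed on the presence of the sequence with 3′UTR length and GC content as covariates, over 11271 genes (92.9% of those tested). Annexins, S100A proteins, the vacuolar proton pump and a list of 38 lysosomal genes were also chosen after the data were seen. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

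The procedure was tested on simulated data with the real means and library sizes. In the knockdown simulation (12136 genes) 49% of genes changed 1.5-fold and 84% of those changed 2-fold were called, with 10 false calls of 143. In the inhibitor simulation (11349 genes) the shares were 63% and 81%, with 8 false calls of 152. In both, a changed list was called and 0 of 20 unchanged lists were. The simulated genes vary independently, and other splits of the real libraries gave a median of 4 called lists in each arm (at most 12 and 8). Alternatives covered other count tests, scalings, filters, pseudocounts and thresholds, voom weights, other list tests, a replicate block, and leaving out each library in turn. Added after seeing the data were edgeR with TMM factors on recovered reads, limma on TMM-scaled values, camera on voom values, leaving out the libraries that stood apart (shLuc 1, shLuc 3 and shOgt 3 together, and vehicle 1 and OSMI-1 5 together), and leaving out genes with AACATGC. Reads, alignments and the hairpin sequences were not analysed here, and the data hold no OGT protein or O-GlcNAc levels.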

Results

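The data were RNA-seq profiles of primary neural stem cells grown from the hippocampus of adult mice, 22 libraries in 4 groups. The series asked how the loss of O-GlcNAcylation bears on the fate of these cells. O-GlcNAcylation is the attachment of single N-acetylglucosamine sugars to nuclear and cytosolic proteins, and O-GlcNAc transferase (OGT) is the enzyme that attaches them. In the knockdown arm, 5 libraries came from cells given a lentiviral short hairpin RNA against Ogt (shOgt) and 6 from cells given a hairpin against luciferase (shLuc), at 10 viral particles per cell for 3 days. In the inhibitor arm, 5 libraries came from cells treated for 24 h with 12.5 µM OSMI-1, a small-molecule inhibitor of OGT, and 6 from cells given vehicle. Total reads per library, recovered from the deposited values, lay between 7.22 M reads (shOgt replicate 3) and 13.2 M reads (shLuc replicate 3) in the knockdown arm. In the inhibitor arm they lay between 4.52 M reads (vehicle replicate 6) and 5.93 M reads, apart from 12.8 M reads in OSMI-1 replicate 4. Levels below are deposited normalized read counts as mean ± SD (n = 6 for shLuc and vehicle, n = 5 for shOgt and OSMI-1). Log2 fold changes are treated over control on the log2(value + 1) scale ± SE, and adjusted p-values of genes are from limma. The tables of the 2 arms were normalized separately, so levels are not compared across them.

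The first comparison asked what changed when Ogt mRNA was lowered. Ogt (ENSMUSG00000034160) lies on GRCm38 chromosome X, 101640060 to 101684351, plus strand. It stood at 831, 1004, 737, 789, 822 and 836 in shLuc replicates 1 to 6 and at 401, 418, 349, 430 and 524 in shOgt replicates 1, 2, 3, 5 and 6. Its mean fell from 836 ± 89.8 to 424 ± 63.9, a log2 fold change of -0.98 ± 0.11 (adjusted p = 1.1e-06), with each shOgt library below each shLuc library. In the inhibitor arm, where the enzyme and not its mRNA was targeted, Ogt mRNA rose from 455 ± 37.6 to 599.9 ± 42.5 (0.40 ± 0.08, adjusted p = 0.001), and each OSMI-1 library lay above each vehicle library. The difference between the log2 fold changes passed the test (adjusted p = 3.6e-22, normal test on the limma estimates). The gene for the enzyme that removes O-GlcNAc, listed under its older symbol Mgea5, fell from 378 ± 59.7 to 281 ± 65.9 after knockdown (-0.44 ± 0.15, adjusted p = 0.029). That call was lost when any of 8 single libraries was left out (shLuc 2, 4, 5 or 6, or shOgt 1, 2, 3 or 5, with adjusted p between 0.051 and 0.078). After OSMI-1, Mgea5 went from 253 ± 38.9 to 277 ± 42.8 (adjusted p = 0.47), and its log2 fold changes differed between the arms (adjusted p = 0.015).

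**Figure D1:**
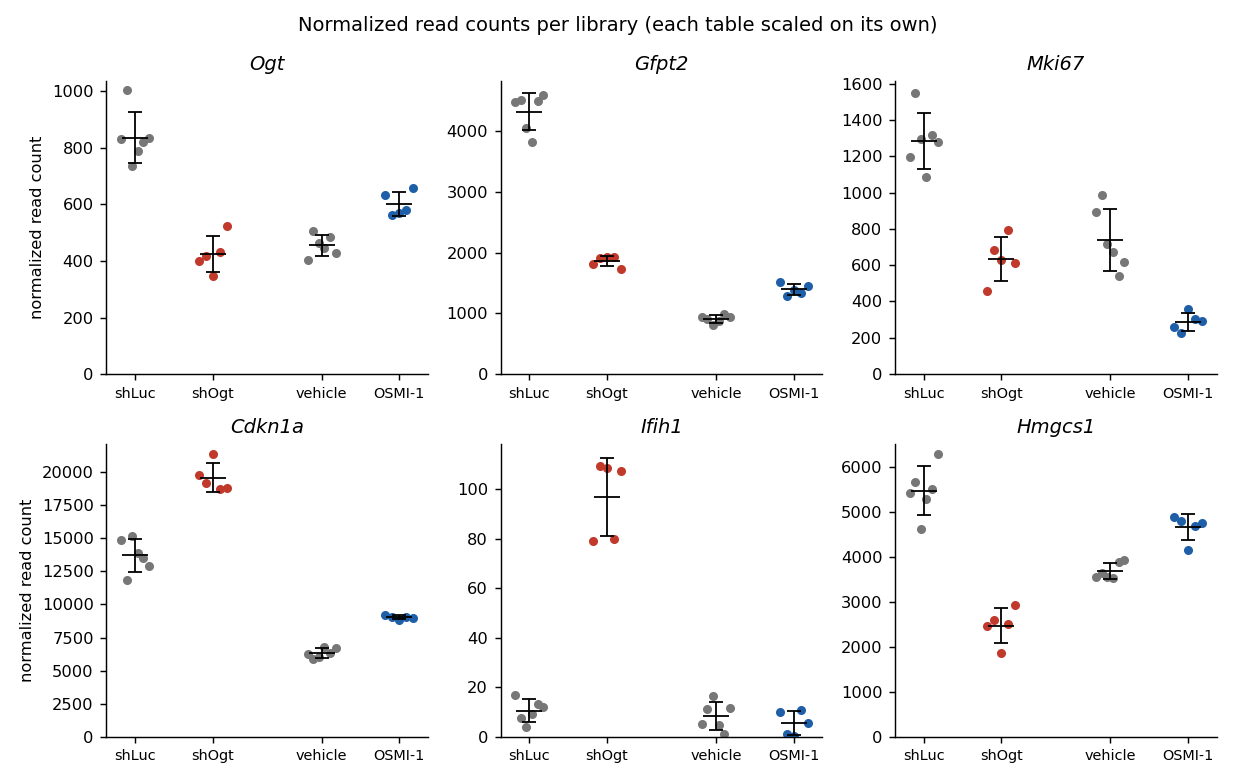
Normalized read counts of Ogt, Gfpt2, Mki67, Cdkn1a, Ifih1 and Hmgcs1 in each library, with the mean ± SD of each group (n = 6, 5, 6 and 5); each table was scaled on its own, so levels compare within an arm. Ogt sits between 349 and 524 in shOgt and between 737 and 1004 in shLuc, and between 563 and 658 in OSMI-1 against 404 to 506 in vehicle.

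Knockdown changed 3855 of 12136 tested genes, of which 1867 rose and 1988 fell, 428 and 262 of them by more than 2-fold. The 6 largest rises among well expressed genes were led by Btg2, an antiproliferative p53 target (406 ± 33.2 to 1673 ± 181, log2 2.04 ± 0.09, adjusted p = 9.6e-12) and Crispld2 (206 to 716). Next came the phospholipid-binding annexin Anxa1 (172 to 588), Pqlc3 (292 to 1012), the microfibril component Fbn2 (344 to 1127) and the membrane protein Tm4sf1 (884 to 2806). The 6 largest falls were led by the heparan sulfate proteoglycan Gpc1 (833 ± 117 to 183 ± 48.4, log2 -2.20 ± 0.15, adjusted p = 2.1e-09). It was followed by the iron-sulfur cluster assembly gene Isca1 (1748 to 505), the phosphatase Ptp4a1 (570.0 to 177), the focal adhesion gene Lims1 (2352 to 741), the small GTPase Rab2b (366 to 119) and the deubiquitinase Usp46 (628 to 217). Each of these 12 genes moved the same way in 5 of 5 shOgt libraries, and the largest limma adjusted p among them was 1.7e-07. All 6 of the fallers carry the 7-base sequence AACATGC in a 3′UTR and none of the 6 that rose does, a search made after the values were seen. Over all 11271 tested genes with a 3′UTR to search, 34.9% of the 447 genes whose 3′UTR holds AACATGC followed by A fell, against 14.3% of the 7803 genes without its 6-base core. Their median log2 fold changes were -0.27 and 0.04 after knockdown, and 0.04 and -0.01 after OSMI-1.

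**Figure D2:**
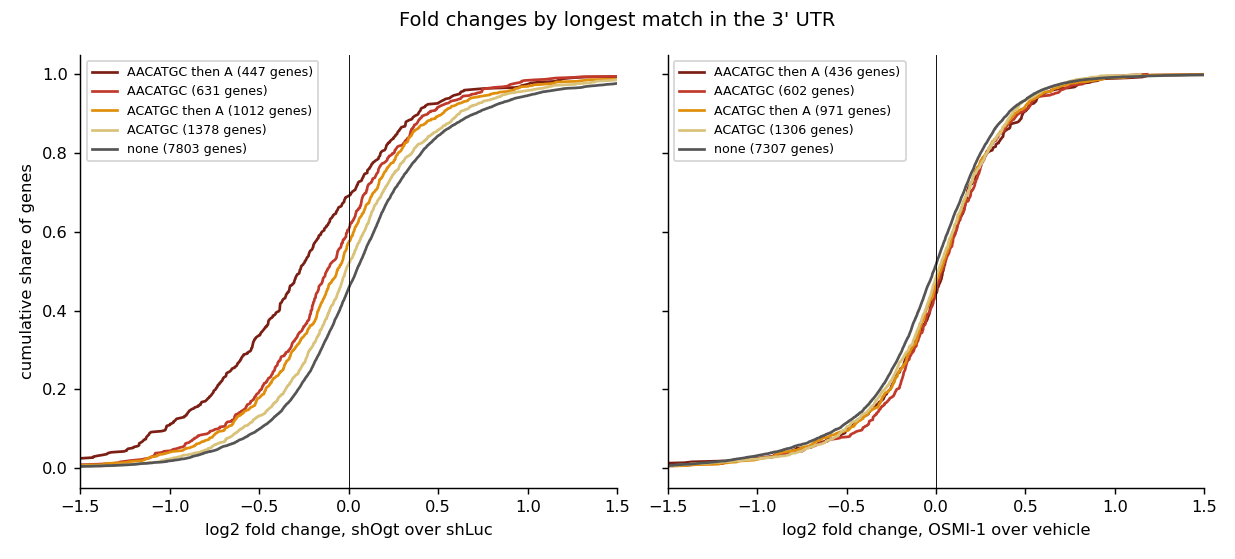
Cumulative share of genes (vertical axis) by log2 fold change (horizontal axis, shown from -1.5 to 1.5) for genes grouped by the longest match to AACATGC in a 3′UTR, after Ogt knockdown and after OSMI-1. After knockdown the curves shift to lower values as the match lengthens, from a median of 0.04 with none to -0.27 with AACATGC then A, and after OSMI-1 the curves lie close together.

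Cell cycle genes fell together after knockdown. Of 22 G1/S and DNA replication genes, 20 fell and none rose (21 fell when adjusted over the list alone), with a median log2 fold change of -0.87 (camera adjusted p = 1.2e-18). Uhrf1, which maintains DNA methylation at replication, fell from 2528 ± 224 to 1112 ± 159. The helicase genes Cdc45 and Mcm5 fell from 1013 ± 78.1 to 450.4 ± 55.7 and from 3229.9 ± 214 to 1599.6 ± 219. All 21 G2/M and mitosis genes fell (21 also when adjusted over the list alone), with a median of -0.73 (camera adjusted p = 1.1e-16). The mitotic kinases Plk1 and Aurkb went from 2974 ± 167 to 1661 ± 158 and from 1982 ± 171 to 939 ± 153. The cyclin Ccnb1 went from 4372 ± 307 to 2568 ± 266. Mki67, the standard marker of cycling cells, fell from 1286 ± 155 to 636 ± 122 (-1.03 ± 0.12, adjusted p = 2e-06). Of 18 p53 target genes 12 rose and 1 fell (14 and 1 when adjusted over the list alone), with a median of 0.54 (camera adjusted p = 1.2e-06). Beside Btg2, the p53 ligase Mdm2 went from 1119.6 ± 70.5 to 1764 ± 133 and the cell cycle inhibitor Cdkn1a from 13698 ± 1236 to 19571 ± 1090.2. These 3 lists also passed camera with an estimated correlation (adjusted p = 0.011, 0.040 and 0.0095).

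Interferon response and immediate early genes rose after knockdown. Of 20 measured members 15 rose and none fell, 15 when adjusted over the list alone, with a median log2 fold change of 1.48 (camera adjusted p = 3.7e-08, and 0.0095 with an estimated correlation). Members with few counts in shLuc can pass the count filter because they rose, and over the 12 members also measured in the OSMI-1 arm the knockdown median was 0.53. The RNA sensor Ifih1 rose from 10.5 ± 4.6 to 96.9 ± 15.8 (3.18 ± 0.34, adjusted p = 8.2e-07). The antiviral genes Rsad2 and Ifit3 rose from 23.8 ± 8.98 to 138 ± 30.4 and from 11.3 ± 5.9 to 65.2 ± 8.02. Of the immediate early genes, which respond within minutes to growth factors and stress, 8 of 12 rose and none fell, and 8 rose and 1 fell when adjusted over the list alone. Their median was 0.65 (camera adjusted p = 0.0012, and 0.026 with an estimated correlation). Egr1 went from 1366 ± 92.8 to 2096 ± 142, Arc from 846 ± 111 to 1572 ± 222 and Egr2 from 49.5 ± 9.89 to 135 ± 8.96. Of 14 microglia and immune markers, 1 passed the count filter, Cd68, at 11.6 ± 6.88 to 18.4 ± 8.47 (limma adjusted p = 0.33, log2 0.73 ± 0.54). The median mean level of the 14 was 0.189. Of 14 endothelial, mural and fibroblast markers 2 passed it. Tek, an endothelial receptor, went from 9.71 ± 8.19 to 29.8 ± 15.9 (adjusted p = 0.039, limma, log2 2.17). It lost its call without shLuc 3 or 4 or shOgt 1, 2, 3 or 6 (adjusted p up to 0.104) and in edgeR (0.066). Of 8 ependymal and choroid plexus markers 4 passed it, and Folr1 rose from 42.1 ± 17.7 to 107 ± 12.9 (adjusted p = 0.0015).

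The cholesterol synthesis, integrated stress response and BMP lists passed camera after knockdown, with less firm calls. Of 20 cholesterol synthesis genes 15 fell and none rose, also 15 when adjusted over the list alone. Their median was -0.41 (camera adjusted p = 7.0e-08, but adjusted p = 0.106 with an estimated correlation). Hmgcs1, an early enzyme of the pathway that carries AACATGC, went from 5466 ± 544 to 2472 ± 391. Fdps went from 8486 ± 1036 to 5584 ± 211 and the squalene epoxidase Sqle from 9787 ± 798 to 6699 ± 708. Of 19 integrated stress response genes 12 fell and none rose, and 12 fell and 1 rose when adjusted over the list alone. Their median was -0.44 (camera adjusted p = 7.3e-06, but adjusted p = 0.19 with an estimated correlation). The members with the smallest p were enzymes of serine and glycine synthesis: Psat1 (5749 ± 397 to 2780.5 ± 174), Phgdh (18017 ± 932 to 11613 ± 1399.7) and Shmt2 (5091 ± 571 to 3067 ± 389). Of 8 BMP and Id genes 4 fell and 1 rose, the same counts as when adjusted over the list alone. The median was -0.48 (camera adjusted p = 0.037, adjusted p = 0.106 with an estimated correlation). The ligand Bmp7 went from 657 ± 76.8 to 264 ± 28.3, the receptor Bmpr1a from 137 ± 30.9 to 68.6 ± 15.5 and the inhibitor of differentiation Id2 from 179.6 ± 24.1 to 109 ± 14.9. The list did not pass without the genes that carry AACATGC, Bmpr1a among them (adjusted p = 0.086), or without the 3 libraries that stood apart (0.078).

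Weaker list calls concerned the endoplasmic reticulum and the mitochondria. Of 17 ER chaperone genes 7 fell and 1 rose, also when adjusted over the list alone. The median was -0.13 (camera adjusted p = 0.040, adjusted p = 0.27 with an estimated correlation). Canx and Calr fell by 0.29 and 0.24 on the log2 scale and Dnajb9 rose by 0.58. That call was lost without shLuc 6 (0.057), shOgt 1 (0.059) or shOgt 3 (0.109). Of 29 nuclear genes of oxidative phosphorylation 9 fell and 1 rose, also when adjusted over the list alone. The median was -0.12 (camera adjusted p = 0.027, adjusted p = 0.56 with an estimated correlation, and 0.113 without shLuc 1). Cox6c (2260.1 to 1382) and Atp5b (34801 to 28973) fell and Ndufa1 (1224 to 1692) rose. In the O-GlcNAc cycling and hexosamine list 4 of 13 genes rose and 4 fell, 5 and 4 when adjusted over the list alone (camera adjusted p = 0.97). Gfpt2, which catalyses the rate-limiting step into the hexosamine pathway, fell from 4319.5 ± 311 to 1861 ± 88 (-1.21 ± 0.07, adjusted p = 1.9e-10). Nagk, which salvages N-acetylglucosamine, rose from 505 ± 60.5 to 1261 ± 46.7 (1.32 ± 0.09, adjusted p = 3e-09). The others that rose were Gnpnat1, Gnpda2 and Amdhd2, and the others that fell were Ogt, Mgea5 and Hcfc1. Of these, Gnpnat1, Gnpda2 and Hcfc1 are named after their values were seen.

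The lists of cell identity did not pass camera after knockdown, and members moved both ways. The fry test, which sets a list against no change and not against other genes, passed for the neuronal (adjusted p = 0.00015) and oligodendrocyte lineage lists (0.0036), both toward lower levels. It also passed for NRF2 targets (0.0074) and glycolysis and hypoxia (0.00033), which did not pass camera, but not for oxidative phosphorylation (0.059), which did. Of 14 neural stem cell genes 2 rose and 3 fell, 2 and 4 when adjusted over the list alone (camera adjusted p = 0.55). The matrix protein Tnc rose from 13096 ± 1312 to 22145 ± 1605 and the intermediate filament Vim from 7745 ± 512 to 10928 ± 1284. The glutamate transporter Slc1a3 fell from 12303 ± 473 to 8547 ± 328. Nes went from 5591 ± 277 to 5228 ± 84.2 (adjusted p = 0.2, log2 -0.10 ± 0.06, limma). The stem cell factor Sox2 went from 65.6 ± 21.3 to 58.7 ± 11.9 (adjusted p = 0.74, log2 -0.12 ± 0.24). Of 9 neuronal genes 2 rose and 4 fell, 2 and 5 when adjusted over the list alone (camera adjusted p = 0.18). Tubb3 rose from 235 ± 38 to 397 ± 25.8. Calb2 fell from 727 ± 154 to 402 ± 33.9 and Map2 from 3375 ± 257 to 2576 ± 163. The newborn neuron marker Dcx had mean values of 1.68 ± 1.86 to 0.743 ± 1.23 and was below the count filter. Of 18 astrocyte genes 2 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.97). Clu rose from 584 ± 53 to 1331 ± 192, and Sox9 (2182 ± 306 to 1391 ± 68.6) and Acsbg1 (18724 ± 1364 to 14025 ± 1173) fell. Gfap, the astrocyte filament, went from 19.1 ± 4.33 to 15.1 ± 7.54 (adjusted p = 0.45, log2 -0.42 ± 0.40, limma). Its shOgt libraries ran from 7.28 to 25.4. Of 8 oligodendrocyte lineage genes 3 fell and 1 rose, also when adjusted over the list alone (median -0.29, camera adjusted p = 0.26). The fallers were the transcription factors Olig1 (18601 ± 1080.0 to 10256 ± 586) and Olig2 (721 ± 170.1 to 403 ± 42.3) and the progenitor proteoglycan Cspg4 (306 ± 44.6 to 163 ± 62.9).

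In the STAT3 list 6 of 17 genes rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.23). Lifr, a cytokine receptor that also carries AACATGC, fell from 561 ± 63 to 234 ± 24.6. Bcl2l1 rose from 2826 ± 185 to 3588 ± 266 and Junb from 169 ± 18.8 to 268 ± 44.7. Stat3 itself went from 2363 ± 150.5 to 2634 ± 139.7 (log2 0.16 ± 0.07, limma adjusted p = 0.076), which passed the threshold without shLuc 6 (0.047). The remaining lists did not pass camera: Notch (1 rose and 1 fell of 11, median 0.24, adjusted p = 0.46), heat shock (3 and 3 of 14, median 0.06, 0.50) and NRF2 targets (3 and 4 of 16, median -0.19, 0.24). Nor did proteasome subunits (none and 5 of 31, median -0.02, 0.23), glycolysis and hypoxia (4 and 5 of 18, median -0.04, 0.13), ribosomal proteins (1 and 2 of 40, median 0.00, 0.97) and SR proteins and CLK kinases (1 and 2 of 15, median -0.15, 0.49). Adjusted over the list alone, these counts were 1 and 1, 3 and 3, 3 and 5, none and 4, 4 and 6, none and none, and 1 and 2. Within them, Pkm, a glycolytic enzyme that carries AACATGC, fell from 111398 ± 7339.6 to 49767 ± 3769 and the small heat shock protein Cryab rose from 2225 ± 243 to 3883 ± 374.

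The second comparison asked what changed after 24 h with the OGT inhibitor. OSMI-1 changed 2815 of 11349 tested genes, of which 1317 rose and 1498 fell, 78 and 294 of them by more than 2-fold. The 6 largest rises among well expressed genes were led by the nuclear long noncoding RNA Malat1 (16668 ± 1299 to 46676 ± 10849.5, log2 1.46 ± 0.10, adjusted p = 2.3e-10) and Uap1l1 (226 to 583). Next came the lysosomal peptidase Dpp7 (134 to 324), the phosphodiesterase Pde1c (152 to 351), the protocadherin Pcdh11x (419 to 965) and the histone gene Hist2h2aa1 (168 to 371), whose reads may be shared with near-identical histone copies. The 6 largest falls were led by the actin-binding calponin Cnn2 (294 ± 36.1 to 62.8 ± 18.4, log2 -2.25 ± 0.17, adjusted p = 5.6e-10). It was followed by the mitotic ubiquitin-conjugating enzyme Ube2c (1134 to 305), the tubulin Tuba1c (484 to 139), the mitotic kinesin Kif2c (385 to 113), the chromatin protein Hmgb2 (2062 to 611) and the lamin Lmnb1 (703 to 216). Each of these 12 genes moved the same way in 5 of 5 OSMI-1 libraries, and the largest limma adjusted p among them was 2.6e-06. Of the 6 fallers 1 carries AACATGC in a 3′UTR (Lmnb1), and of the 5 risers with a 3′UTR to search none does.

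Cell cycle genes fell after OSMI-1 as well, mitotic genes most. All 21 G2/M genes fell (21 also when adjusted over the list alone), with a median log2 fold change of -1.34 (camera adjusted p = 7.6e-38, and 0.00062 with an estimated correlation). Beside Ube2c, the cyclins Ccnb1 and Ccna2 fell from 2136 ± 103 to 709.6 ± 55 and from 1444 ± 102 to 474 ± 40.4. Of 22 G1/S genes 21 fell and none rose, also 21 when adjusted over the list alone (median -0.77, camera adjusted p = 5.2e-23, and 0.0011 with an estimated correlation). The ribonucleotide reductase genes Rrm2 and Rrm1 fell from 2419 ± 115 to 1175 ± 57.7 and from 2191 ± 115 to 1049.7 ± 109, and the helicase subunit Mcm7 from 1361 ± 46.1 to 784 ± 59. Mki67 fell from 738 ± 169.8 to 287 ± 49 (-1.34 ± 0.13, adjusted p = 8.3e-08). Of 17 p53 targets 12 rose and none fell, 13 when adjusted over the list alone (median 0.36, camera adjusted p = 3.7e-08, and 0.019 with an estimated correlation). The stress cytokine Gdf15 went from 337 ± 34.3 to 649 ± 58.8, Cdkn1a from 6319 ± 358 to 9037 ± 150.0 and Btg2 from 369 ± 16.2 to 541 ± 40.3.

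The hexosamine, cholesterol and ribosomal protein lists passed camera after OSMI-1, with less firm calls. Of 13 O-GlcNAc cycling and hexosamine genes 6 rose and 1 fell, 7 and 1 when adjusted over the list alone. The median was 0.35 (camera adjusted p = 0.0061, but adjusted p = 0.14 with an estimated correlation). Uap1l1, a paralog of the enzyme that makes UDP-N-acetylglucosamine, rose from 226 ± 29.4 to 583 ± 31.4 and Gfpt2 from 909 ± 64.4 to 1392 ± 88.8. Amdhd2, which deacetylates N-acetylglucosamine phosphate, rose from 221 ± 28.7 to 356 ± 35.4. Of 20 cholesterol synthesis genes 13 rose and none fell, 17 and 1 when adjusted over the list alone. The median was 0.29 (camera adjusted p = 1.2e-06, but adjusted p = 0.14 with an estimated correlation). Insig1 rose from 1149.7 ± 104 to 1785 ± 87.8, Hsd17b7 from 666 ± 47.5 to 932 ± 55.2 and Hmgcs1 from 3686 ± 178 to 4655 ± 287. Of 40 ribosomal protein genes 18 fell and none rose, and 20 fell when adjusted over the list alone. The median was -0.22 (camera adjusted p = 1.2e-06, but adjusted p = 0.64 with an estimated correlation). Rpl3 went from 4042 ± 280.1 to 2786 ± 193, Rpsa from 3737 ± 477 to 2463 ± 217 and Rps15 from 1395 ± 143 to 903 ± 168. Pseudogene copies make counts in this family uncertain, and a camera p as small came in 39 of 100 assignments of the libraries to groups. Of 29 nuclear oxidative phosphorylation genes 6 rose and 2 fell, also when adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.025, adjusted p = 0.66 with an estimated correlation). Ndufa1 (586 to 927) and Cox5b (1165 to 1560.2) rose and Atp5b (18149.6 to 13837) fell. This call was lost without vehicle 5 (0.070), OSMI-1 5 (0.086) or OSMI-1 6 (0.165), and a p as small came in 36 of 100 assignments. Of 15 SR protein and CLK kinase genes, which act in splicing, 6 fell and 1 rose, also when adjusted over the list alone. The median was -0.16 (camera adjusted p = 0.025, adjusted p = 0.35 with an estimated correlation). Srsf3 went from 1762 ± 152 to 982 ± 117, Srsf7 from 1371 ± 103 to 997 ± 141 and Tra2b from 1426 ± 139 to 1069 ± 64.1.

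Cell identity lists did not pass camera after OSMI-1, while fry passed for the neural stem cell (adjusted p = 0.00039) and neuronal lists (0.00023), both toward lower levels. Outside these, fry passed for the STAT3 (0.0029), BMP and Id (0.0056) and ER chaperone (0.041) lists, which did not pass camera. It did not pass for oxidative phosphorylation (0.22) and ribosomal proteins (0.074), which did. Of 12 neural stem cell genes 1 rose and 5 fell, also when adjusted over the list alone (median -0.27, adjusted p = 0.12). The growth factor receptor Egfr rose from 775 ± 51.8 to 1112 ± 96.1. Slc1a3 fell from 5318 ± 277 to 3455 ± 170.4 and Vim from 6095 ± 660.4 to 4329 ± 594. Nes went from 2892 ± 153 to 3027 ± 184 (limma adjusted p = 0.48, log2 0.07 ± 0.06). For Sox2 the levels were 61.8 ± 12.9 to 59 ± 12.3 (adjusted p = 0.82, log2 -0.07 ± 0.20). Of 9 neuronal genes 1 rose and 3 fell, 1 and 4 when adjusted over the list alone (camera adjusted p = 0.24). Calb2 fell from 97.9 ± 11.6 to 35.2 ± 5.21, Gap43 from 114 ± 10.7 to 57.1 ± 16 and Tubb3 from 88.5 ± 14.1 to 50.2 ± 6.02. The riser, named after its value was seen, was Map2 (1862 ± 189 to 2459.8 ± 379). Among 17 astrocyte genes 5 rose and 4 fell, 5 and 5 when adjusted over the list alone (camera adjusted p = 0.91). S100b rose from 58.3 ± 13.7 to 142 ± 33.3, and the receptor Fgfr3 and Aldoc fell from 170.4 ± 16.3 to 64.6 ± 13.7 and from 1498 ± 155 to 995 ± 102. Gfap (8.97 ± 4.65 to 3.2 ± 2.82) and Dcx (1.54 ± 2.34 to 1.97 ± 2.5) were below the count filter. Of 9 oligodendrocyte lineage genes 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.91). Mbp went from 19.5 ± 6.73 to 8.4 ± 9.48 and Olig1 from 10465 ± 947 to 12254 ± 1378 (limma adjusted p = 0.027 and 0.035, log2 -1.91 and 0.22). Mbp lost its call without vehicle 2, 3, 4 or 5 or OSMI-1 4 or 5 (adjusted p up to 0.089, log2 -1.31 without OSMI-1 4) and in edgeR (0.12). Olig1 lost it without vehicle 2, 4, 5 or 6 or OSMI-1 1, 2 or 6 (up to 0.103). Bcas1 went from 326 ± 60 to 269.8 ± 60.9 (adjusted p = 0.15).

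In the STAT3 list 1 of 17 genes rose and 1 fell after OSMI-1, and 1 rose and none fell when adjusted over the list alone (camera adjusted p = 0.17). Serpina3n, an acute phase gene, rose from 20 ± 7.87 to 56.7 ± 13.5. Socs3, the feedback inhibitor of the pathway, went from 24.6 ± 10.1 to 11.4 ± 6.47 (limma adjusted p = 0.049, log2 -1.16). Its call was lost without vehicle 2, 3, 4, 5 or 6 or OSMI-1 1, 5 or 6 (adjusted p up to 0.153) and in edgeR (0.060). Stat3 went from 1094 ± 96.3 to 1211 ± 68.7 (log2 0.15 ± 0.07, adjusted p = 0.15). Of 12 interferon genes past the count filter 1 rose and 1 fell, none and 1 when adjusted over the list alone (camera adjusted p = 0.91). The faller was Ifit2 (48.1 ± 8.3 to 21.5 ± 10) and the riser, named after its value was seen, was Stat2. Of 12 immediate early genes 1 fell, also when adjusted over the list alone, Arc (381 ± 36.8 to 303 ± 26; camera adjusted p of the list = 0.91). Of 19 integrated stress response genes 4 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.20), and Psat1 fell from 3520.2 ± 159.6 to 2009 ± 185. Of 8 BMP and Id genes 1 rose and 3 fell, 2 and 3 when adjusted over the list alone (camera adjusted p = 0.78), with Id1 at 156 ± 13.2 to 95 ± 10.9. Of 14 microglia and immune markers none passed the count filter, of 14 endothelial, mural and fibroblast markers 1 did, and of 8 ependymal markers 3 did. Foxj1, a regulator of motile cilia, fell from 126 ± 32.2 to 53.3 ± 10.9. Lists with few calls that did not pass camera were Notch (none rose and 2 fell of 10, median -0.08, adjusted p = 0.91), ER chaperones (2 and 5 of 17, median -0.09, 0.28), heat shock (1 and 3 of 14, median -0.02, 0.91) and NRF2 targets (4 and 3 of 16, median -0.02, 0.91). The others were proteasome subunits (1 and 1 of 31, median -0.02, 0.91) and glycolysis and hypoxia (1 and 3 of 17, median 0.01, 0.91). Adjusted over the list alone, these counts were none and 1, 2 and 6, 1 and 3, 4 and 3, none and 1, and 1 and 5. In these, the iron-storage gene Ftl1 rose from 16691 ± 1087 to 24092 ± 1282 and Gapdh fell from 11239.6 ± 869 to 8613 ± 732.

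**Figure D3:**
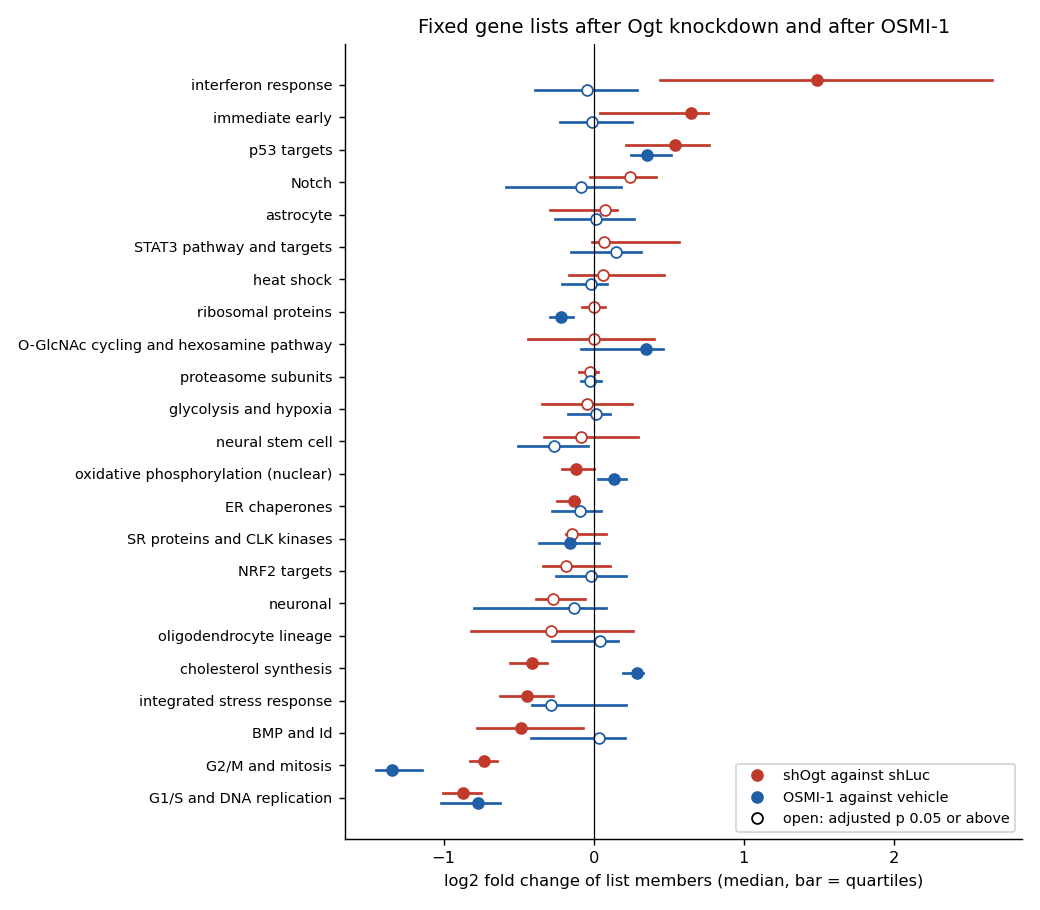
Median log2 fold change (treated over control) of the measured members of each gene list, with bars from the lower to the upper quartile, after Ogt knockdown and after OSMI-1; open symbols mark lists whose camera adjusted p was 0.05 or more. G2/M genes lie at -0.73 and -1.34, interferon genes at 1.48 after knockdown (20 members, against 12 after OSMI-1), and cholesterol synthesis genes at -0.41 and 0.29.

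The third comparison asked which genes moved the same way after Ogt knockdown and after the OGT inhibitor. Among 11269 genes tested in both arms, which share no libraries, 636 fell in both where 260 would be shared by independent lists (Fisher's exact test, one-sided, p = 1.2e-137, odds ratio 4.74). A further 307 rose in both, where 202 would be shared (Fisher's exact test, one-sided, p = 4.1e-16, odds ratio 1.82). Both tests take genes as independent units, although genes such as those of the cell cycle move together. Their p-values are thus too small and do not measure the spread between libraries. Another 150 rose after knockdown and fell after OSMI-1, and 209 did the reverse. So 943 of the 1302 genes called in both (72.4%) moved the same way. Across all 11269 genes, which are not independent replicates, the log2 fold changes correlated weakly (Pearson r = 0.163, bootstrap 95% interval 0.137 to 0.188; Spearman rho = 0.188, 0.167 to 0.206). Among genes down in both were the thymidine kinase Tk1 (-1.31 after knockdown, -1.32 after OSMI-1) and the histone gene Hist1h2ab (-1.40 and -2.01). The others were the cell cycle transcription factor E2f8 (-1.31 and -1.53), the cytokinesis kinase Cit (-1.21 and -1.26) and the kinesin Kif14, which carries AACATGC (-1.63 and -1.19). Among genes up in both were Cpt1a, the enzyme that admits fatty acids to mitochondria (1.30 and 0.90), Emp3 (1.47 and 1.20), Isoc2b (1.05 and 1.35), Samd9l (1.59 and 1.17) and Crebrf (1.39 and 1.79). The last 4 have low counts in at least 1 arm. Samd9l lost its OSMI-1 call without vehicle 4 or OSMI-1 4 (adjusted p up to 0.070). Crebrf lost its knockdown call without shLuc 4 or 6 or shOgt 1, 2 or 3 (up to 0.080) and in edgeR (0.068).

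**Figure D4:**
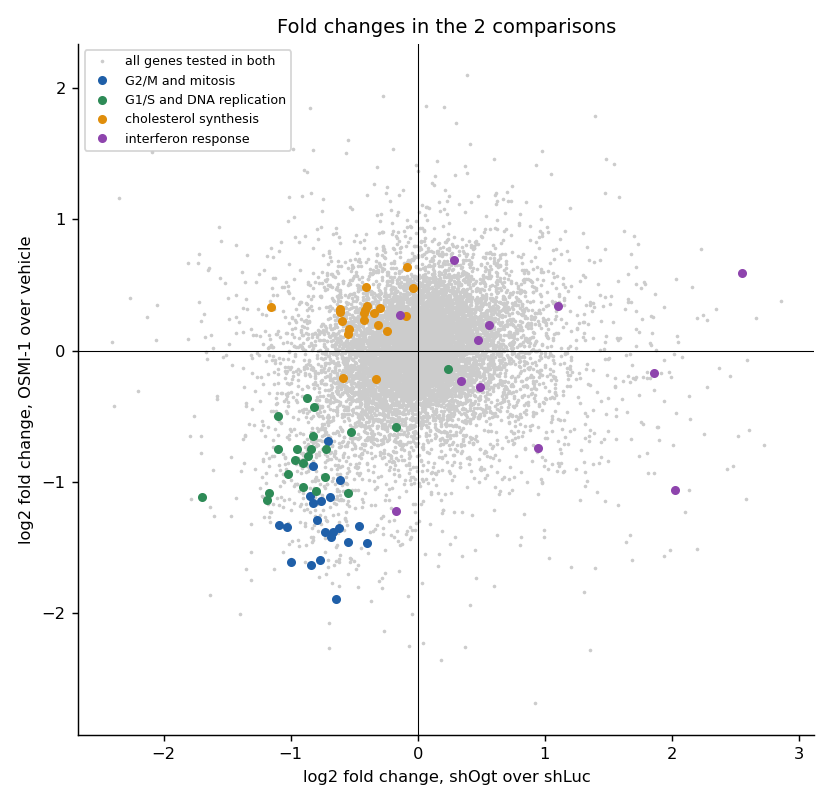
Log2 fold change after OSMI-1 (vertical axis) against that after Ogt knockdown (horizontal axis) for each of the 11269 genes tested in both arms, with 4 gene lists in colour. G2/M and G1/S genes lie mostly in the lower left quadrant, interferon genes spread to the right, and cholesterol synthesis genes lie mostly in the upper left, where 17 of 20 had lower log2 fold changes after knockdown.

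The fourth comparison asked where the response to knockdown and to OSMI-1 differed. For 2991 genes (26.5%) the log2 fold changes differed past adjusted p = 0.05, with 1519 higher and 1472 lower after knockdown (normal test on the limma estimates). The normal test makes very small p-values too small. With DESeq2 folds and standard errors 2672 genes differed, and in a joint edgeR fit 2569. By list the smallest p was that of cholesterol synthesis genes: 17 of 20 had a lower log2 fold change after knockdown and none a higher one (cameraPR adjusted p = 8.8e-17, and 2.6e-10 at a preset correlation of 0.05). G2/M genes fell further after OSMI-1, with 15 of 21 differing (1.5e-11). G1/S genes (0.65) and p53 targets (0.48) did not pass the test of a difference. Interferon genes were higher after knockdown, 7 of the 12 measured in both (0.0039), as were immediate early genes (0.0060). The hexosamine list was lower (0.0034), with 5 of 13 genes lower and 2 higher. It holds Ogt, the hairpin's target, and was not tested without Ogt. Single genes that parted were Gfpt2 (-1.21 after knockdown and 0.61 after OSMI-1, adjusted p = 2.7e-74), Vim (0.49 and -0.50, 3.3e-16) and Tubb3 (0.77 and -0.80, 4.3e-12). Mki67 (0.19) and Slc1a3 (0.39) did not pass. Genes that rose after knockdown and fell after OSMI-1 by the most included the hydroxysteroid dehydrogenase family member Akr1c14 (2.20 and -1.51), Pdgfrl (1.99 and -1.52), Rassf7 (1.36 and -2.28), Fam26e (1.94 and -1.57) and Pfkfb1 (1.40 and -1.65). The reverse held for Pcdh11x (-0.91 and 1.18), Ppp1r16b (-0.98 and 1.02), Shisa9 (-1.01 and 1.17), Abhd3 (-1.86 and 1.78) and Bricd5 (-2.35 and 1.16). Several of these genes have low counts, and 4 lost a call when libraries were left out. After OSMI-1, Fam26e lost its call without any of 9 single libraries (all but OSMI-1 1 and 2, adjusted p up to 0.13) and in edgeR (0.11). Bricd5 lost it without vehicle 3, 4, 5 or 6 or OSMI-1 2, 4, 5 or 6 (up to 0.138). After knockdown, Pfkfb1 lost its call without shLuc 5 or shOgt 3, 5 or 6 (up to 0.081), and Abhd3 without shLuc 2, 5 or 6 or shOgt 3 (up to 0.063). Without shOgt 3 the log2 fold change of Abhd3 was -1.15. Knockdown ran for 3 days and the inhibitor for 24 h, so time and means of acting on OGT differ together between the arms.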

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

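The tests of list and gene differences between the arms and the number-of-sites test were set before their results were seen, whereas the 7-base search, its match-length test and the immune marker and OSMI-1 tests of the interferon list were chosen after. Ogt mRNA moved in opposite directions in the arms (adjusted p of the difference 3.6e-22; log2 -0.98 after knockdown, in 5 of 5 libraries, and 0.40 after OSMI-1, in 5 of 5). Mgea5 differed too (adjusted p = 0.015; log2 -0.44 and 0.13). By list, differences between the arms passed cameraPR for cholesterol synthesis (adjusted p = 8.8e-17, medians -0.41 and 0.29), G2/M (1.5e-11, -0.73 and -1.34), oxidative phosphorylation (0.0015, -0.12 and 0.14), ribosomal proteins (0.0024, 0.00 and -0.22), the hexosamine list (0.0034, 0.00 and 0.35), interferon (0.0039, 0.53 and -0.04 over the 12 members in both), immediate early (0.0060, 0.65 and -0.01), the integrated stress response (0.016, -0.44 and -0.29), oligodendrocyte lineage (0.029, -0.75 and 0.08 over the 7 members in both) and glycolysis and hypoxia (0.029, -0.07 and 0.01 over the 17 in both). Over all 8 oligodendrocyte members measured in the knockdown arm the median was -0.29. The hexosamine list holds Ogt, the hairpin's target, and was not tested without Ogt. At a preset correlation of 0.05 the ribosomal (0.051), integrated stress response (0.073), oligodendrocyte (0.064) and glycolysis (0.103) differences no longer passed.

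Of 364 sets of values, 24 held 1 value far from the others, where chance alone gives about 1 in 20, or 18.2. Each set was 1 gene or 1 library measure within 1 group of libraries. The OSMI-1 replicate 4 library had 12.8 M reads. In shLuc 1, Mgea5 was at 261, Vim at 8737, Shmt2 at 6254 and Ppp1r16b at 423. Ogt was at 1004 in shLuc 2 and Mdm2 at 988 in shLuc 3. In the shOgt libraries, Mgea5 was at 395 in replicate 6, Isca1 at 682 in replicate 5, Lims1 at 581 in replicate 1 and Cspg4 at 274 in replicate 3. In vehicle 1, Sox2 was at 87.8, Pde1c at 116 and Aldoc at 1793. Dcx was at 5.97 in vehicle 5, and in vehicle 6 Uap1l1 was at 283 and Ftl1 at 18759. In OSMI-1 replicate 4, Sox2 was at 37.4, Hmgcs1 at 4159 and Srsf3 at 777. Hist2h2aa1 was at 315 in OSMI-1 1, Gap43 at 84.7 and Btg2 at 471 in OSMI-1 5, and Bricd5 at 44.7 in OSMI-1 6.

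Other assignments of the 11 libraries of an arm to groups of 6 and 5 were drawn 100 times, the real one included. The count of 3855 genes after knockdown was reached by 1 of 100, the real one. The highest other was 2112, from a split that set shLuc 2 to 6 against shLuc 1 and the 5 shOgt libraries together. For OSMI-1 the 2815 genes were reached by 1 of 100, with 1 gene in the highest other. The 2991 differing genes were reached by 1 of 100 (highest other 692). Chance is thus argued against for the counts of called genes. For the differing genes these splits only set the real libraries against no effect in either arm. They cannot test whether the arms responded alike, because other splits called a median of 0 genes in each arm. The 943 genes in the same direction were also reached by 1 of 100 (highest other 0). That comparison cannot test agreement between the arms, because the other splits called a median of 0 genes in each arm and so left almost nothing to overlap. The 8 lists after OSMI-1 were reached by 3 of 100. The highest other was also 8, so chance is made less likely for that number but is not excluded. The 10 lists after knockdown were reached by 9 of 100 (highest other 12), so chance is not excluded for that number. The median over the other splits was 4 lists in each arm. For single lists after knockdown, a camera p as small came in 1 of 100 splits for G1/S, G2/M and p53 targets, 2 for immediate early, 3 for interferon and for BMP and Id, 8 for cholesterol, 9 for the integrated stress response, 16 for ER chaperones and 31 for oxidative phosphorylation. After OSMI-1 it came in 1 for G1/S, G2/M and p53 targets, 2 for the hexosamine list, 3 for cholesterol, 10 for SR proteins and CLK kinases, 36 for oxidative phosphorylation and 39 for ribosomal proteins. The identity lists did not pass camera. For them it came after knockdown in 2 for neuronal, 24 for oligodendrocyte lineage, 49 for neural stem cell and 93 for astrocyte. In the same order these numbers were 10, 94, 3 and 90 after OSMI-1.

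Genes with AACATGC in a 3′UTR had lower log2 fold changes after knockdown, by -0.24 ± 0.019 (SE) with 3′UTR length and GC content in the model, the lowest of 15715 sequences scanned, in 1078 of 11271 genes. The sequence was picked as the lowest in a model that already held length and GC content, so that value alone is no test of them. Without these covariates its effect was -0.245, so they changed it little. Another 404 sequences of the same bases hold neither AACATG nor ACATGC. The lowest of these, CATGCAA, which shares CATGC with it, had t = -5.42 against -12.6. AACATGC was picked as the lowest of all sequences scanned, so these had to lie higher. Only the size of the gap argues against base composition. A response to lower OGT activity shared with OSMI-1 is argued against by an effect of 0.0092 ± 0.014 there. A candidate explanation is base pairing of the hairpin with these mRNAs. The drop was graded by match length, with AACATGC then A at -0.36 ± 0.029 relative to genes without the core, without covariates (0.052 ± 0.022 after OSMI-1). AACATGC and ACATGCA ranked 1 and 2 in the same scan. That order is thus partly set by the choice of sequence and is no separate test. With length and GC content in the model, genes with 2 or more AACATGC sites lay lower than those with 1 (-0.14 ± 0.053). The sequence occurs in the Ogt 3′UTR at GRCm38 chromosome X, 101682399 to 101682405 (last exon, 22 of 22 in transcript Ogt-201 and 23 of 23 in Ogt-202) and 101683051 to 101683057 (exon 22 of Ogt-201), plus strand, but the hairpin's own sequence was not analysed, so this stays a hypothesis.

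Interferon genes rose after knockdown, in 15 of 20 members (median 1.48, and 0.53 over the 12 also measured in the OSMI-1 arm). Immune cells in the shOgt cultures are argued against by the markers of such cells, of which 1 of 14 passed the count filter, at a level of 11.6 to 18.4 for Cd68. A response shared with OSMI-1 is argued against by the difference between the arms (adjusted p = 0.0039, cameraPR; 7 of 12 members higher after knockdown). A response to this hairpin and a response to 3 days of lower Ogt cannot be told apart, because 1 hairpin group against Ogt was profiled. The biological explanation, that lower OGT over 3 days raises these genes, stays open and untested.

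Cholesterol synthesis genes fell after knockdown and rose after OSMI-1 by camera at the preset correlation, but neither call held with an estimated correlation (adjusted p = 0.106 and 0.14). Matches of the 7-base sequence in the list's 3′UTRs are argued against as the whole cause. The 13 of 20 members without its 6-base core there had a median of -0.41 ± 0.070 after knockdown (bootstrap SE over members, not libraries). Matches in the coding sequence of these 13 were not checked. Among all genes without the core in a 3′UTR, the 727 with AACATGC in the coding sequence averaged -0.12 ± 0.021 relative to the rest. A match in a regulator upstream of the list was not excluded. GC content and transcript length are argued against by a difference of medians of -0.72 ± 0.052 (bootstrap SE over members) after their trend was taken out. Values were at hand for 20 of 20 members. The arms differ in time and in the means of acting on OGT, and either may be the source.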

How the results depend on the processing

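The alternatives edgeR with TMM, limma on TMM-scaled values and camera on voom values, the settings without the 7-base sequence genes and those without libraries that stood apart were chosen after seeing the data. Of 151 alternative values for the 6 counts of genes and lists, 140 stayed within 1.5 times the reported count and 11 were lower. With an absolute log2 fold above 1 added, knockdown called 690 genes and OSMI-1 372, and at adjusted p = 0.01 they called 2538 and 1698, with 551 in the same direction in both. These are narrower thresholds by construction. With an estimated correlation 5 lists passed after knockdown and 3 after OSMI-1, and with cameraPR on the deposited log2 folds 6 and 4. Restricted to genes above the median expression, 6 lists passed after knockdown and 1884 genes differed between the arms, where fewer genes were tested. For the list counts on deposited folds and with an estimated correlation the cause was not tested. Leaving out 1 library at a time gave 3208 to 3897 genes and 9 to 10 lists after knockdown, 2428 to 2680 genes and 7 to 8 lists after OSMI-1, 830 to 947 genes in the same direction and 2688 to 3079 differing. Without genes that carry AACATGC, knockdown called 3446 genes and 8 lists, and without the 3 libraries that stood apart 3956 genes and 7 lists. Without vehicle 1 and OSMI-1 5, OSMI-1 called 2539 genes and 7 lists, with 866 genes in the same direction and 2873 differing. There the calls of oxidative phosphorylation (0.061), Mbp (0.071), Arc (0.055), Fam26e (0.085) and Pfkfb1 (0.090) were lost. Of the values for single lists, 878 kept their side of the threshold, 45 lost it and 11 gained it, and of those for single genes 4119 kept it, 117 lost it and 6 gained it. The direction of Sox2, which was called nowhere, turned in 3 fits that left out 1 library. They gave 0.017 after knockdown without shLuc 5 (range -0.23 to 0.017), and 0.030 and 0.078 after OSMI-1 without vehicle 1 and without OSMI-1 4 (range -0.13 to 0.078); the cause was not tested. With upper-quartile scaling 56.6% of the knockdown calls rose against 48.4% in the reported fit.

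Replicate numbers did not pair the libraries in general. Deviations from the group means of libraries with 1 number correlated between -0.0086 and 0.16 in the knockdown arm and between -0.099 and 0.051 in the inhibitor arm. Of 10 pairs 1 correlated best with its own number, replicate 3 of the knockdown arm (0.16). Its libraries, shLuc 3 and shOgt 3, also lay together on the third principal component (-33.6 and -34.0), so a link between them is not excluded. With the replicate number as a block, 3962 and 2376 genes and 9 and 8 lists were called, with 847 genes in the same direction and 2936 differing.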

Other observations

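All groups in this part were chosen after the data were seen, from gene families sharing a symbol stem. The lysosomal list came instead from textbook knowledge once the proton pump had been seen. Each is thus a description that needs other data. The p-values below, also those of differences between the arms, come from the same data as the choice and are no separate tests. Genes of the lysosome rose after OSMI-1. Of 18 subunits and accessory proteins of the vacuolar proton pump, which acidifies lysosomes, 14 rose and none fell. Their median log2 fold change was 0.40 (camera adjusted p over 4 families = 1.2e-11, and 0.00050 with an estimated correlation). Over the wider Atp symbol stem 21 of 58 genes rose and 4 fell (median 0.21). The camera adjusted p there was 0.00060, but 0.16 with an estimated correlation. Atp6v0b rose from 1509 ± 83.9 to 2799 ± 274 and Atp6ap1 from 2718 ± 262 to 4399 ± 337. Of 38 lysosomal enzymes and membrane proteins 24 rose and none fell (median 0.44, camera adjusted p = 9.1e-14, and 0.012 with an estimated correlation). The protease Ctsd rose from 6906 ± 454 to 12309 ± 1442 and Grn from 1652 ± 78.2 to 2792 ± 394. After knockdown 4 of 19 pump genes rose and 3 fell (median 0.05, camera adjusted p = 0.41), and 16 of 38 lysosomal genes rose and 3 fell (median 0.15, camera adjusted p = 0.0049, but adjusted p = 0.15 with an estimated correlation). The arms differed for the pump (adjusted p = 1.4e-06, cameraPR) and the lysosomal list (1.4e-05).

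Annexin and S100A genes rose after knockdown. Of 8 annexins 7 rose and none fell (median 1.39, camera adjusted p over 4 families = 4.0e-09, and 0.00067 with an estimated correlation). Over the 199 symbol stems scanned, the annexins' camera adjusted p was 2.0e-07, and 0.033 with an estimated correlation. Anxa2 rose from 3637 ± 242 to 10156 ± 774. All 7 S100A genes rose (median 1.05, camera adjusted p = 1.6e-06, and 0.042 with an estimated correlation), among them S100a10 (1561 ± 207 to 3563 ± 326), which forms a complex with Anxa2. S100a6 had few counts in shLuc (4.72 ± 5.18 to 29.0 ± 7.29) and can pass the count filter because it rose. The list was not tested without S100a6. The stem scan placed the S100A genes in a group of 11 genes with the stem S, whose camera adjusted p was 0.00028, and 0.66 with an estimated correlation. After OSMI-1, 1 of 7 annexins rose and 2 fell (median -0.23, camera adjusted p = 0.34), and of 6 S100A genes none rose and 1 fell (median -0.24, 0.075). The arms differed for the annexins (adjusted p = 3.0e-14, cameraPR) and for the S100A genes (8.4e-09). The sign of each of these medians held under TMM, upper-quartile and size-factor scaling.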
